A study of Homo sapiens with 8 samples.

How the data were processed

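The series holds 8 RNA-seq libraries of JEG-3, an established human choriocarcinoma cell line used as a model of the trophoblast. Per the labels, 4 groups of 2 libraries cross genotype (control or HAVCR1 knockout) with treatment (mock or poly I:C, a synthetic double-stranded RNA). The series title speaks of a knockdown and the sample labels of a knockout; the samples are called knockout here. Per the labels' protocols, total RNA was extracted with Trizol and made into DNBSEQ mRNA libraries. Dose and duration of poly I:C, the position of the edit, the number of clones, the strand setting of the counting and the origin of the replicates are not given in the sources used here. If the replicates are not separate cultures, the p-values measure only the spread between these libraries, which may be technical.

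The authors deposited raw read counts per gene in 2 tables, 1 for the mock and 1 for the poly I:C libraries. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 2.0.5, DESeq2 1.20.0 and the hg19 build, without saying which step each served. All columns of the deposited counts are whole numbers and were used as deposited. Total counts were 54626359 to 61386435 per mock library and 31734208 to 32425841 per poly I:C library. The tables list different gene IDs, 62703 for mock and 63568 for poly I:C, and 52191 IDs are shared once the version is removed. Only 25275 of the shared IDs carry the same version, so the tables were counted against different gene annotations. Shared IDs held 99.24% to 99.5% of each library's counts, and the tests used these IDs. Because each treatment has its own table, a difference between poly I:C and mock cannot be told apart from a difference between the tables. Knockout and control libraries of 1 treatment sit in the same table.

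Symbols came from a table of gene names, which matched 52181 of the shared IDs. The reference annotation at hand, GENCODE release 29, is of another build than hg19, so no coordinates are given and it served only for chromosome and gene order. Genes that share reads with a near-identical copy are uncertain, and so are overlapping and antisense genes.

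Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group, minimum count 10). All 8 libraries entered 1 fit with 4 groups, which share the estimate of spread, and 18651 genes were tested. The 5 comparisons were knockout against control under mock and under poly I:C, poly I:C against mock in each genotype, and the difference of the poly I:C response between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM are counts per megaread of the TMM-scaled library, computed here from the deposited counts, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes were derived from the F statistic. For a gene with no count in a group, the fold is a lower bound against 3 counts over the group, which covers counting error only.

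The test design, the alternatives, 29 gene lists, a panel of genes and the rule for named genes were fixed before the data were examined. Named genes are the panel, the 8 highest and 8 lowest log2 fold changes among called genes with a mean of at least 5 CPM in a group and no overlap between the libraries of the 2 groups (for the interaction, in any group and without the overlap condition), and up to 4 members of each list with the smallest p. Lists with at least 4 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, then with an estimated correlation, and with fry. The markers of hepatocyte lines had 0 and those of HEK293-like or neuronal cells 2 tested members, so neither list was tested.

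The spread differed between the tables. The biological coefficient of variation was 14.6% over the mock libraries alone, 1.94% over the poly I:C libraries alone and 9.59% over all 8. The mean chi-square per gene between replicates, which is 1 for sampling noise alone, was 32.8 for mock control, 25.6 for mock knockout, 1.86 for poly I:C control and 1.84 for poly I:C knockout. The poly I:C replicates therefore differed by little more than sampling noise, yet by more than it, and were kept as 2 libraries each. The shared estimate of spread is too small for the mock libraries and larger than the spread seen between the poly I:C libraries. If the poly I:C replicates are not separate cultures, it need not be too large for that treatment.

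The procedure was tested on simulated counts drawn for the real genes, with 200 genes changed in both knockout comparisons. With equal spread in all libraries, 95% of genes changed by a log2 fold of 1 were called in the mock comparison (18260 genes) and 97% in the poly I:C comparison. With each table's own spread, 83.5% were called under mock and 20.5% of the mock calls were false; under poly I:C 89.5% were called and 0% of calls were false. With no changed gene, edgeR gave 0 calls in these simulations. Each setting was drawn once, with the same spread for all genes of a table and genes drawn independently. Spread that differs between genes, or that genes share between cultures, was therefore not covered by these rates. The rates with each table's own spread also take the spread between libraries as that between cultures. At a log2 fold of 0.5 and each table's own spread, 2.5% of changed genes were called under mock and 0% after poly I:C, so small changes can be missed.

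Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, at least 1 CPM in 2 libraries, only the 4 libraries of a comparison, the replicate number as a block, an added fold threshold and leaving out each library. Added after seeing the data were limma voom with sample weights per treatment, leave-one-out fits of the gene lists, 1 list without HAVCR1, and tests without genes at 0 throughout 1 table.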

Results

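Gene expression was measured by RNA-seq in JEG-3 choriocarcinoma cells that were control or HAVCR1 knockout, each after mock treatment or poly I:C, with 2 libraries per group. HAVCR1, also called TIM-1, is a cell surface receptor for phosphatidylserine. The series asks whether its loss alters the interferon response of these cells. The mock libraries held 54626359 to 61386435 counts and the poly I:C libraries 31734208 to 32425841. Values below are mean CPM ± SD (n = 2), with log2 fold changes ± standard error and adjusted p from edgeR's quasi-likelihood test.

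The targeted gene was examined first. HAVCR1 (ENSG00000113249) was lower in every knockout library than in every control library of the same treatment. Under mock it measured 182 ± 16 CPM in control and 72 ± 0.3 CPM in knockout cells, 39.5% of control (log2 fold change -1.34 ± 0.07, adjusted p = 8.2e-05). After poly I:C it measured 85 ± 2 CPM in control and 28 ± 0.66 CPM in knockout cells, 33% of control (-1.6 ± 0.08, adjusted p = 3.9e-05). The raw counts were 11762 and 8942 in mock control, 3970 and 4302 in mock knockout, 2794 and 2693 in poly I:C control, and 882 and 913 in poly I:C knockout. Transcript thus remained in the knockout libraries, and counts over the whole gene do not show whether it encodes the protein.

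**Figure D1:**
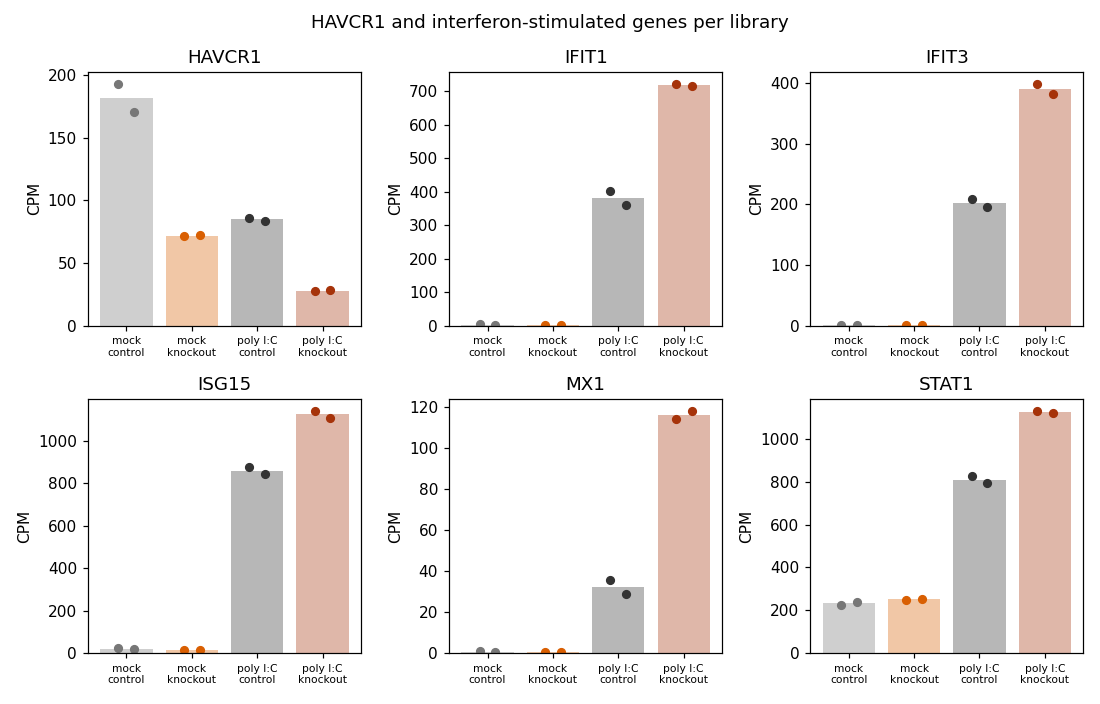
CPM (linear axis from 0) of HAVCR1 and 5 interferon-stimulated genes in the 4 groups; bars are means and points the 2 libraries of each group. HAVCR1 fell to 39.5% (mock) and 33% (poly I:C) of control, and IFIT1 after poly I:C was 382 CPM in control and 719 CPM in knockout cells.

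Knockout and control cells were compared at rest. Of 18651 genes tested, 458 were higher and 505 lower in mock knockout cells. The transcription factor GLI3 rose from 6.62 ± 0.41 to 30.5 ± 3.7 CPM (log2 fold change 2.2 ± 0.11, adjusted p = 8.2e-05), and FBXO38, a ubiquitin ligase component, from 1.29 ± 0.24 to 10.3 ± 0.84 CPM (2.98 ± 0.16, adjusted p = 8.2e-05). PODXL, a sialomucin of the cell surface, had a log2 fold change of 4.43 ± 0.6, although its knockout libraries differed (6.88 ± 5.6 CPM). ABLIM1 rose by 2.61. DPPA3 fell from 32.1 ± 0.64 to 6.53 ± 1.6 CPM (-2.3 ± 0.14, adjusted p = 1e-04), and LIMCH1 and RAB38 had log2 fold changes of -1.9 and -1.76. PPFIA4 had -3.19 with an adjusted p of 0.048, and its control libraries varied by more than their mean (42.5 ± 48 CPM). SMN2 had -2.73, which is uncertain because it shares reads with SMN1. PPFIA4 lost its call without any 1 of mock knockout replicates 1 and 2 and the 4 poly I:C libraries.

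Among the fixed lists, 3 of 20 tested hypoxia and glycolysis genes were lower and 0 higher (10 lower adjusted over the list alone), with a median log2 fold change of -0.37 and camera adjusted p = 2.5e-07 (adjusted p = 0.52 with an estimated correlation). DESeq2 called 6 lower, and edgeR with only the 4 mock libraries 1. Without mock control replicate 1 the median was -0.14 with 2 higher and 4 lower (adjusted p = 0.019), and without mock control replicate 2 it was -0.55 with 0 higher and 17 lower. The called members were VEGFA, a growth factor of blood vessels (-0.63), the glucose transporter SLC2A1 (-0.49) and hexokinase HK2 (-0.42). In cholesterol synthesis, 4 of 21 genes were higher and 0 lower (14 higher adjusted over the list alone; median 0.32, camera adjusted p = 1.8e-07, adjusted p = 0.52 with an estimated correlation), among them LSS (0.55) and SC5D (0.53). The higher members numbered 11 without mock control replicate 2, 13 without mock knockout replicate 1, 2 without any 1 poly I:C library and 1 without mock knockout replicate 2, where the median was 0.16. In the integrated stress response list, 5 of 20 genes were lower and 1 higher (9 and 3 adjusted over the list alone; median -0.31, camera adjusted p = 0.00016, adjusted p = 0.52 with an estimated correlation), including STC2 (-0.56) and the serine synthesis enzymes PSAT1 (-0.55) and PHGDH (-0.41). Its counts were 8 lower and 0 higher without mock control replicate 1 (median -0.2), 8 and 3 without mock control replicate 2, 8 and 1 without mock knockout replicate 1, 3 and 0 without mock knockout replicate 2, and 1 and 0 without any 1 poly I:C library. This list was not called after poly I:C (median -0.04, 3 lower and 1 higher, camera adjusted p = 0.27). The receptor subunit IFNAR1 rose from 14.5 to 31.1 CPM (1.1 ± 0.08, adjusted p = 0.00021) and the kinase JAK1 from 102 to 151 CPM (0.57 ± 0.06, adjusted p = 0.0018), both part of interferon signalling. They were the 2 higher of 13 interferon genes and receptors, of which 1 was lower (2 and 1 adjusted over the list alone). The lower 1 was IFNL2, with 8 counts in the mock control and 0 in the mock knockout libraries (adjusted p = 0.048), and it kept its call only without mock control replicate 2 among the 8 fits that left out 1 library. Of 20 cytotrophoblast and trophoblast stem cell genes, KRT7 (0.74), YAP1 (0.49) and LRP2 (0.48) were higher and GATA3 (-0.36) was lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.18). Of 25 genes of syncytiotrophoblast hormones and fusion, 0 were higher and 3 lower (1 and 7 adjusted over the list alone; median -0.05, camera adjusted p = 0.027, adjusted p = 0.52 with an estimated correlation). That list lost its call without mock control replicate 2 (adjusted p = 0.095), mock knockout replicate 1 (0.49, median 0.02), poly I:C control replicate 1 or 2 (0.095) or poly I:C knockout replicate 1 (0.1); its median was -0.14 and -0.08 without mock control replicate 1 and 2 and -0.25 without mock knockout replicate 2. Its counts were 2 higher and 5 lower without mock control replicate 1, 0 and 5 without mock control replicate 2 and 1 and 3 without mock knockout replicate 1. The 3 called with all libraries were SDC1 (-0.68), the steroidogenic enzyme CYP11A1 (-0.39) and ERVFRD-1, which encodes a fusion protein (-0.49). LRP2 and ERVFRD-1 lost their call without either mock knockout library or any 1 of the 4 poly I:C libraries, HK2, PHGDH and GATA3 without mock knockout replicate 2 or any 1 of the 4 poly I:C libraries, PSAT1 without any 1 of the poly I:C libraries, and SC5D without mock knockout replicate 2.

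The interferon-stimulated genes were examined at rest. Of 60 tested, 2 were higher and 8 lower in knockout cells (2 and 13 adjusted over the list alone), with a median log2 fold change of -0.21 and camera adjusted p = 7.9e-05 (adjusted p = 0.52 with an estimated correlation). With only the 4 mock libraries 0 were higher and 1 lower of 49 tested (edgeR; 2282 of all genes had an unadjusted p under 0.05), with voom weights per treatment 0 and 1 of 60, the lower 1 being TDRD7 in both, and with DESeq2 1 and 11. IFIT2 was 1.3 CPM in control and 0.506 CPM in knockout cells (-1.37 ± 0.22, adjusted p = 0.01), the RNA sensor IFIH1 6.13 and 2.84 CPM (-1.12 ± 0.14, adjusted p = 0.0032), and TDRD7 14.9 and 5.02 CPM (-1.56 ± 0.11, adjusted p = 0.00021). The 2 higher members were CMPK2, 0.824 and 2.89 CPM (1.83 ± 0.35, adjusted p = 0.02), and RSAD2, 0.115 and 0.295 CPM (1.34 ± 0.3, adjusted p = 0.047), the latter named to complete the count after its values were seen. RSAD2 lost its call without any 1 of the 8 libraries, and CMPK2 without mock control replicate 1, mock knockout replicate 2 or any 1 of the 4 poly I:C libraries. Without mock control replicate 1 the list was no longer called (adjusted p = 0.12, median -0.02), and without mock knockout replicate 2 IFIT2 was not. The list had 4 higher and 8 lower members without mock control replicate 1, 2 and 20 without mock control replicate 2, 1 and 5 without mock knockout replicate 1, and 0 and 3 without mock knockout replicate 2 or any 1 poly I:C library. With only the 4 mock libraries, 46 genes were higher and 67 lower over all genes. Leaving out mock control replicate 1 gave 758 and 866, mock control replicate 2 gave 1729 and 1463, mock knockout replicate 1 gave 723 and 638, mock knockout replicate 2 gave 194 and 173, and leaving out a poly I:C library gave 120 to 124 and 160 to 188.

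Knockout and control cells were then compared after poly I:C. Interferon-stimulated genes were higher in knockout cells: of 60 tested, 37 were higher and 1 lower (42 and 2 adjusted over the list alone), with a median log2 fold change of 0.55. RSAD2, which encodes the antiviral enzyme viperin, rose from 9.65 ± 1.1 to 52.6 ± 0.9 CPM (2.45 ± 0.11, adjusted p = 3.3e-05); it was also called higher at rest in the fit of all libraries, and the difference of its response did not pass the test (1.1, adjusted p = 1). The antiviral GTPase MX1 rose from 32.3 ± 5.1 to 116 ± 2.7 CPM (1.85 ± 0.17, adjusted p = 0.001). IFIT5 (1.01), IFIT3 (0.95), OAS1 (0.94), IFIT1 (0.91), IFI35 (0.86), IFIT2 (0.85) and OASL (0.72) were also higher. STAT1 rose from 810 ± 21 to 1130 ± 4.9 CPM (0.48 ± 0.06, adjusted p = 0.0037), and ISG15 from 858 ± 23 to 1130 ± 26 CPM (0.39 ± 0.09, adjusted p = 0.034). The list had a camera adjusted p of 4e-60, of 0.085 with an estimated correlation, and a fry adjusted p of 0.0065.

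Of 16 tested genes of double-stranded RNA sensing, 7 were higher and 1 lower (8 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.0026, adjusted p = 0.22 with an estimated correlation). The higher genes included IFIH1 (0.81), TLR3 (0.8), RIGI (0.64) and DHX58 (0.6). The lower 1, also the lower 1 of the interferon-stimulated genes, was TRIM25 (-2.54, adjusted p = 0.021), named to complete the count. TRIM25 had few counts, with 1.76 and 0.993 CPM in the control and 0.188 and 0.281 CPM in the knockout libraries. IFIH1, RIGI, DHX58, EIF2AK2 and TRIM25 are also members of the interferon-stimulated list. Of 13 interferon genes and receptors, 3 were higher and 0 lower (6 and 0 adjusted over the list alone; median 0.48, camera adjusted p = 2.8e-07, adjusted p = 0.22 with an estimated correlation). With any 1 mock library left out, 5 of these were called higher, and with any 1 poly I:C library left out 2 were. In the latter fits edgeR called 0 sensing genes (7 to 8 higher at an unadjusted p under 0.05), with a median of 0.09 without knockout replicate 1, and without mock control replicate 1, 2 sensing genes were lower. The 3 called with all libraries were IFNL1, a type III interferon (10.8 against 19.5 CPM, 0.85 ± 0.13), IFNAR1 (0.83) and JAK1 (0.64). IFNB1 had 1.98 CPM in control and 2.97 CPM in knockout cells, and CXCL10 14.9 and 16.5 CPM; neither difference passed the test (adjusted p = 0.25 and 0.59). Hypoxia and glycolysis genes were lower, 14 of 20 with 0 higher (18 lower adjusted over the list alone; median -0.67, camera adjusted p = 7.9e-19, adjusted p = 0.22 with an estimated correlation). HK2 (-0.69), SLC2A1 (-0.47), ALDOA (-0.44) and ANKRD37 (-1.11) were among them.

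Over all genes, 510 were higher and 645 lower after poly I:C, and with RLE scaling 689 and 555, so which direction held more calls depended on the scaling. FBXO38 (2.65), GLI3 (2.14), the receptor NRP1 (2.18), ITGB6 (2.14), LAIR2 (2.02) and MX2 (2.2) were among the highest. The lowest included PLTP, a phospholipid transfer protein (-2.5), TCEAL7 (-2.48), DPPA3 (-2.11) and PPFIA4 (-3.06). With only the 4 poly I:C libraries, whose replicates differed by little more than sampling noise, 3900 genes were higher and 3763 lower. Leaving out 1 poly I:C library gave 26 to 39 higher and 21 to 36 lower genes, without mock control replicate 1 the counts were 1736 and 1757, and without mock control replicate 2 they were 1785 and 1706. In these fits without a poly I:C library, 5 to 10 interferon-stimulated genes were called higher and 0 lower, and the list median was 0.56 to 0.63; the hypoxia and glycolysis list then had 0 called genes, with a median of -0.59 to -0.67. Of the interferon-stimulated and sensing genes named above, RSAD2, MX1, MX2, IFIT5 and IFI35 kept their call in each of these fits, IFIT2 lost it without poly I:C control replicate 2 or knockout replicate 1, and IFIT3 without these or control replicate 1. OAS1, IFIT1, OASL, STAT1, ISG15, IFIH1, TLR3, RIGI and DHX58, with IFNL1, PLTP and PPFIA4, lost it without any 1 of the 4 poly I:C libraries, PPFIA4 also without either mock knockout library, and TCEAL7 without either knockout library.

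The genes called in the 2 knockout comparisons were set against each other. The comparisons share no library, but both took each gene's spread from 1 fit. A gene with a small estimate of spread can thus be called in both, so the numbers for independent lists are only a reference. Any lasting difference between the knockout and control cells, from the edit or not, would also recur in both. The overlap therefore does not show its cause. Of the higher genes 230 were shared, against 12.5 for independent lists, and of the lower genes 301, against 17.5 (Fisher's exact test, one-sided, log10 p = -250.8 and -330.6; genes are not independent). DPPA3, GLI3 and FBXO38 are examples. Only 4 genes were called in opposite directions, and these were ISG15, IFIH1, IFIT2 and HELZ2, lower in knockout cells at rest and higher after poly I:C; for ISG15 the difference between the treatments did not itself pass the test (0.8, adjusted p = 0.14). With only the 4 mock libraries, and with voom weights per treatment, all 4 lost their call under mock. In the fits that left out 1 library, ISG15 kept its call under mock only without mock control replicate 2, HELZ2 lost it without mock knockout replicate 2 or any 1 poly I:C library, and IFIT2 without mock knockout replicate 2. After poly I:C, ISG15, IFIH1 and HELZ2 lost theirs without any 1 poly I:C library, and IFIT2 without poly I:C control replicate 2 or knockout replicate 1.

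**Figure D2:**
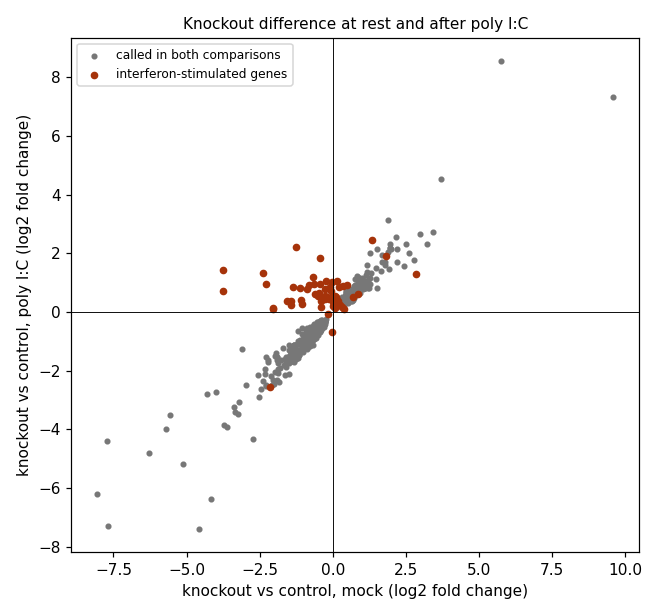
Fitted log2 fold change of knockout against control under mock (x axis) and after poly I:C (y axis), for genes called in both comparisons (grey) and 60 interferon-stimulated genes (red). Grey points lie along the diagonal, while most red points lie above 0 on the y axis, with a median of 0.55, and around -0.21 on the x axis.

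Poly I:C was compared with mock in each genotype; these values carry the difference between the 2 tables. In control cells, 59 of 60 interferon-stimulated genes were higher and 0 lower (60 higher adjusted over the list alone), with a median log2 fold change of 4.5 (camera adjusted p = 5.7e-141, adjusted p = 0.014 with an estimated correlation). In knockout cells 58 were higher and 0 lower (60 higher adjusted over the list alone), with a median of 5.25 (camera adjusted p = 9.1e-187, adjusted p = 0.014 with an estimated correlation). The medians did not change with genes at 0 under mock set to their lower bound. Only 2 genes in control and 5 in knockout cells were concerned, so this says little about the effect of low mock counts. IFIT1 rose from 2.85 to 382 CPM in control cells (7.04 ± 0.28, adjusted p = 5.2e-08) and from 1.64 to 719 CPM in knockout cells (8.76 ± 0.3, adjusted p = 1.9e-08). ISG15 rose by 5.43 ± 0.11 and 6.23 ± 0.11, RIGI by 8.7 ± 0.13 and 9.8 ± 0.13, and STAT1 by 1.8 ± 0.06 and 2.16 ± 0.06 on the log2 scale. IFNL1 had no count in any mock library and was at least 409-fold higher in control and at least 749-fold higher in knockout cells.

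Of 8 tested genes of MHC class I antigen presentation, 7 were higher in control cells (8 adjusted over the list alone; median 2.04, camera adjusted p = 4e-05, adjusted p = 0.19 with an estimated correlation) and 7 in knockout cells (7 adjusted over the list alone; median 2.27, camera adjusted p = 7.1e-07, adjusted p = 0.18 with an estimated correlation). B2M, the light chain of class I molecules, rose from 81.8 to 729 CPM and from 58 to 784 CPM, and the peptidase ERAP1 by 1.41 and 1.86 on the log2 scale. BIRC5, an inhibitor of apoptosis active in mitosis, had a log2 fold change of -1.69 in both genotypes. It lay far from the median of its list, cell cycle (-0.23 in control and -0.24 in knockout cells). In that list 16 of 35 genes were lower and 2 higher in control cells, and 17 and 2 in knockout cells. Its camera adjusted p was 0.01 and 0.024, and 0.94 and 0.99 with an estimated correlation. HAVCR1 itself was lower after poly I:C, by a log2 fold change of -1.1 ± 0.07 in control and -1.36 ± 0.08 in knockout cells.

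Over all genes, 2902 were higher and 2143 lower in control cells, and 2704 and 2223 in knockout cells. DESeq2 gave 2414 and 2473 in control cells and 2481 and 1749 in knockout cells, so which direction held more calls in control cells depended on the tool. Of the genes tested, 416 had no count in any mock library, IFNL1 among them, and 106 none in any poly I:C library; for these, table and treatment cannot be told apart. In each genotype 415 of the called genes were among the 416; tests without genes at 0 throughout 1 table gave 2409 higher and 1936 lower in control cells and 2243 and 2029 in knockout cells. NCOA4 (501 CPM in mock control), CD24 and KMT2B were at 0 in all poly I:C libraries, and BDP1 (125 CPM in poly I:C control) and NDUFA6 at 0 in all mock libraries. ALDOA, at 25.8 CPM in mock control and 1260 CPM in poly I:C control, also differed between mock and poly I:C in both genotypes. Leaving out poly I:C control replicate 1 or 2 gave 1799 and 1870 higher and 960 and 984 lower genes in control cells, and leaving out mock control replicate 1 gave 3602 lower genes there. In knockout cells the lower genes numbered 3339 without either mock control library, 1372 and 1378 without poly I:C control replicate 1 and 2, and 869 and 821 without poly I:C knockout replicate 1 and 2.

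The difference between the responses tests whether knockout and control cells respond to poly I:C to the same extent, and a constant difference between the tables cancels in it. Interferon-stimulated genes responded more in knockout cells, with a median difference of 0.81 on the log2 scale; 6 of 60 were called higher and 0 lower (39 and 0 adjusted over the list alone), while DESeq2 called 27 and 0 and voom with weights per treatment 4 and 0. The list had a camera adjusted p of 8.4e-104, of 0.034 with an estimated correlation, and a fry adjusted p of 0.062. Double-stranded RNA sensing was also called (median 0.15, 1 of 16 genes higher, 7 adjusted over the list alone, camera adjusted p = 1.3e-10, adjusted p = 0.047 with an estimated correlation); without mock control replicate 1, 4 of its genes were higher, and its median was 0.14 to 0.29 over all fits that left out 1 library (0.22 without mock control replicate 1, 0.24 without mock knockout replicate 2 and 0.21 to 0.29 without a poly I:C library). IFIH1, RIGI, DHX58, EIF2AK2 and TRIM25 belong to both of these lists, and IFIH1 was the sensing gene called. The results of the lists are thus not independent. Of single genes, 9 were called higher and 1 lower over all genes tested. IFIT2 (2.22 ± 0.24, adjusted p = 0.016), IFIH1 (1.93 ± 0.17, adjusted p = 0.0066), TDRD7 (1.92 ± 0.15, adjusted p = 0.0059), HELZ2 (1.05), IFIT5 (1.04 ± 0.11) and APOL6 (0.82 ± 0.1) responded more in knockout cells. NMI (0.79), named because it completes the count and outside the rule for named genes, did as well. Part of some of these differences lies in the mock levels. TDRD7 was lower in knockout cells under mock (-1.56) and not called after poly I:C (0.36, edgeR adjusted p = 0.068). IFIT2 and IFIH1 were lower under mock (-1.37 and -1.12) and higher after poly I:C (0.85 and 0.81), while IFIT5 hardly differed under mock (-0.03). The list median was -0.21 under mock and 0.55 after poly I:C, and several members had few mock counts. For GCA (2.24) and SMN2 (2.54), knockout cells were lower under mock (0.8 against 4.17 and 1.07 against 7.17 CPM) and close to control after poly I:C (10.2 against 11.3 and 22.4 against 25.5 CPM). The SMN2 value is uncertain because SMN2 shares reads with SMN1. If the tables assigned such reads differently, that difference need not cancel. The imprinted RNA H19 had a difference of -2.52 ± 0.31. MX1 (2.28), IFIT1 (1.73) and STAT1 (0.36) did not pass the test (adjusted p = 0.19, 0.45 and 0.55).

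Without any 1 of the 4 poly I:C libraries, 0 genes were called in either direction, against 812 genes with an unadjusted p under 0.05 in the fit of all libraries; DESeq2 called 52 higher and 4 lower. Without mock control replicate 1 the calls were 211 higher and 287 lower, without mock control replicate 2 they were 43 and 4, and without mock knockout replicate 1 and 2 they were 5 and 9, and 8 and 7. Without either mock knockout library, IFIT2, HELZ2, APOL6, NMI and H19 lost their call. The interferon-stimulated genes called were 23 higher and 2 lower without mock control replicate 1, 24 and 0 without mock control replicate 2, and 3 and 0 without mock knockout replicate 1. The median over all 60 stayed between 0.65 and 0.91 in these fits.

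Across 4526 genes called in control cells and counted in both tables, the response in knockout cells correlated with that in control cells (Pearson r = 0.95, Spearman rho = 0.962, across genes, which are not independent replicates), with a slope of 0.94. For the 58 interferon-stimulated genes among them the slope was 1.17 and the median difference 0.87. Both responses carry the difference between the tables, which raises the correlation.

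**Figure D3:**
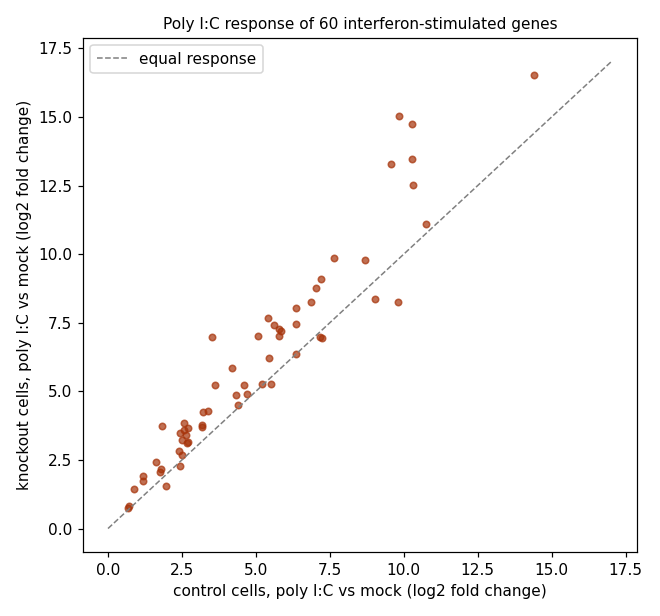
Fitted log2 fold change of poly I:C against mock for 60 interferon-stimulated genes in control cells (x axis) and knockout cells (y axis); each point is a gene and the dashed line marks equal responses. Most points lie above the line, with a median difference of 0.81.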

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

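The tests of explanations in this part were chosen after the results were seen, while the test of the difference of the responses was planned. The difference of the poly I:C response between genotypes, tested as an interaction, marked 10 genes and 8 lists. The genes were SMN2 (2.54), GCA (2.24), IFIT2 (2.22), IFIH1 (1.93), TDRD7 (1.92), HELZ2 (1.05), IFIT5 (1.04), APOL6 (0.82), NMI (0.79) and H19 (-2.52), as log2 differences, knockout minus control. SMN2 is uncertain because it shares reads with SMN1. The lists, with the median log2 difference of their members, were interferon-stimulated genes (0.81), double-stranded RNA sensing (0.15), MHC class I antigen presentation (0.37), apoptosis and pyroptosis (0.18), the integrated stress response (0.12), the unfolded protein response (0.13), hypoxia and glycolysis (-0.29) and mitochondrially encoded genes (0.09). With an estimated correlation, interferon-stimulated genes (adjusted p = 0.034) and double-stranded RNA sensing (adjusted p = 0.047) stayed under 0.05 and the other 6 lists did not (adjusted p = 0.29 to 0.85). The lists that stayed under 0.05 share members, IFIH1 among them. The hypoxia and glycolysis median in this test was -0.49 with 12 genes lower without mock control replicate 1, and -0.08 without mock control replicate 2 (adjusted p = 0.14). Without a poly I:C library it was -0.2 (control replicate 1) to -0.28, and that of double-stranded RNA sensing 0.21 to 0.29; the latter was 0.24 without mock knockout replicate 2.

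After poly I:C, 37 of 60 interferon-stimulated genes were higher in knockout cells and 1 was lower, and the list was not called with an estimated correlation (adjusted p = 0.085). Without poly I:C control replicate 1 or 2, 8 and 5 were called higher, and without knockout replicate 1 or 2, 7 and 10. A shift in the scaling of the libraries would move other genes alike, but the list median lay 0.57 above the median of the other genes tested, a difference that scaling does not make. Whether single cultures respond this differently whatever their genotype stays open and cannot be told apart from the genotype: between mock control replicates the list shifted by a median of 0.23, below the list median of 0.55. By the bound first set this would have counted against the explanation; the bound was tightened after 0.23 was seen, because resting levels do not measure how the response varies and the poly I:C replicates varied by only 1.94% against 14.6% for mock. A difference between clones or in poly I:C uptake may also contribute, and an effect of HAVCR1 loss, which the design names, stays open as a hypothesis; neither was tested.

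Some well expressed genes were at 0 in every library of 1 table, 104 of them in the mock and 43 in the poly I:C table with at least 5 CPM in the other. A changed model of the gene itself between the annotations would make this more frequent among IDs whose version differs. It was 0.779% there (123 of 15782) and 0.837% among IDs of the same version (24 of 2869). Fisher's exact test, two-sided, gave p = 0.73 for this difference. The test pooled both tables, which can hide opposite differences, so it does not decide on a changed model for either table. Most of the 24 genes of the same version were at 0 in the mock table. Of those at 0 in the poly I:C table, only RPS7P1 and ZNF321P had the same version. For genes at 0 in the poly I:C table, NCOA4 among them, a changed model stays open, because the tables were not tested separately. Another gene of 1 annotation only that overlaps the genes at 0, making their reads ambiguous, may be the cause. Of the IDs found in the poly I:C table alone, only 2.94% have a position in the annotation at hand, so such overlaps could not be examined. No biological explanation was tested.

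Of 20 hypoxia and glycolysis genes, 3 were lower in knockout cells under mock and 14 after poly I:C, with median log2 differences of -0.37 and -0.67; with an estimated correlation the list was called in neither (adjusted p = 0.52 and 0.22). Without mock control replicate 1 or 2 the median under mock was -0.14 and -0.55 with 4 and 17 genes lower, and without any 1 poly I:C library edgeR called 0 after poly I:C (15 to 18 lower at an unadjusted p under 0.05). The list median after poly I:C lay at -0.66 relative to the other genes, which argues against scaling. Between the mock control replicates the same list shifted by a median of 0.41, which is larger in size than the difference under mock, so a difference between cultures, for example in density, cannot be told apart from the genotype.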

How the results depend on the processing

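The voom fits, the leave-one-out fits of the gene lists, the phosphatidylserine list without HAVCR1 and the tests without genes at 0 throughout 1 table were chosen after seeing the data; the other alternatives were planned. Of the 129 named gene results called, 62 lost their call in at least 1 leave-one-out fit and 36 under another alternative besides the fold threshold, and no named gene value changed sign in any alternative that gave one (2178 values, 1789 on the same side of the threshold). With only the 4 libraries of a comparison, knockout against control gave 46 higher and 67 lower genes under mock and 3900 and 3763 after poly I:C, and poly I:C gave 1343 lower genes in control cells. Such a fit differs at once in its spread, residual degrees of freedom, filter and scaling, and these were not separated. With voom weights per treatment the counts were 195 and 192 under mock, 3377 and 3531 after poly I:C, and 5 higher in the difference of the responses. With a log2 fold of at least 1, a stricter criterion, they were 113 and 184 under mock, 102 and 215 after poly I:C, 1931 and 587 for poly I:C in control cells and 641 lower in knockout cells. DESeq2 gave 1147 higher genes for knockout after poly I:C, and 52 higher and 4 lower in the difference of the responses. The filter at 1 CPM gave 862 higher genes for knockout after poly I:C and 0 lower in the difference of the responses (edgeR; 812 genes had an unadjusted p under 0.05 in the fit reported, and DESeq2 gave 4); the cause was not tested for DESeq2 or for this filter.

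Leaving out 1 library gave 120 to 1729 higher and 160 to 1463 lower genes for knockout under mock, 26 to 1785 and 21 to 1757 after poly I:C, 1799 to 4073 and 960 to 3602 for poly I:C in control cells, 1967 to 3328 and 821 to 3339 in knockout cells, and 0 to 211 and 0 to 287 in the difference of the responses. In these fits the lone library is assumed to vary like the other groups, and without a poly I:C library the spread is taken mostly from mock libraries. The slope between the responses was 0.79 to 0.98 and the median difference 0.65 to 1.05 over those interferon-stimulated genes that each fit called in control cells, which are not all 60. For lists, adjusted p without 1 library reached 0.12 for interferon-stimulated genes under mock (lowest 2.3e-08), 0.11 for phosphatidylserine receptors (lowest 0.0032) and 0.14 for hypoxia genes in the difference of the responses (lowest 5.6e-26); under mock it reached 0.49 for syncytiotrophoblast genes (0.095 to 0.1 without 4 other libraries, lowest 0.00075), 0.26 for interferon genes and receptors (0.053 to 0.1 without 6 others, lowest 0.005), 0.61 and 0.059 for matrix genes (lowest 8.1e-06) and 0.49 and 0.053 for histones (lowest 3.3e-05). The other lists tested this way stayed under 0.05.

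With an estimated correlation, which allows for members that vary together, the adjusted p under mock was 0.52 for interferon-stimulated genes, hypoxia, cholesterol synthesis, the integrated stress response and syncytiotrophoblast genes, 0.54 for interferon genes, matrix genes and histones, and 0.43 for phosphatidylserine receptors and the neighbours of HAVCR1. After poly I:C it was 0.085 for interferon-stimulated genes and 0.22 for double-stranded RNA sensing, hypoxia, interferon genes and the neighbours of HAVCR1, 0.59 for the unfolded protein response and 0.63 for heat shock. It was 0.19 and 0.18 for MHC class I genes after poly I:C in control and knockout cells, and 0.63 for hypoxia in the difference of the responses. Under mock, phosphatidylserine receptors and the neighbours of HAVCR1 had estimated correlations of 0 and -0.03, below the preset 0.01. Members that vary together thus do not explain why these lists lost their call. Even with 59 of 60 interferon-stimulated genes higher after poly I:C in control cells it was 0.014, so lists not called this way may still differ. Fry gave 0.16 for interferon-stimulated genes under mock, 0.14 for hypoxia, cholesterol synthesis, syncytiotrophoblast genes, matrix genes and histones, 0.099 for the integrated stress response and interferon genes, 0.14 for the unfolded protein response and heat shock after poly I:C, and in the difference of the responses 0.062 for interferon-stimulated genes and 0.8 for hypoxia. The deviations of same-numbered replicates were weakly correlated (-0.08 to 0.14, the latter between mock control and mock knockout). The poly I:C replicates differed by little more than sampling noise, so these values cannot show whether the numbers pair the libraries. With the replicate number as a block, the counts were 532 and 577, 622 and 741, 2960 and 2154, 2681 and 2189, and 8 and 1 in the order of the comparisons, and phosphatidylserine receptors had an adjusted p of 0.066 and interferon genes of 0.11, both under mock. Without HAVCR1 in the list the adjusted p of phosphatidylserine receptors was 0.4 in the fit without a block. Depth limits the genes with no count in a group, for which only a lower bound of the fold was given (IFNL1, at least 409-fold in control cells). Fits at equal depth were not run.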

Other observations

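Of the tests in this part, the 1 on chromosome 5 was written before its result was seen, and the leave-one-out values of the lists were added afterwards. FN1, the matrix protein fibronectin, was higher in knockout cells under mock (779 against 1200 CPM, log2 fold change 0.62, adjusted p = 0.0018) and after poly I:C (855 against 1240 CPM, 0.54, adjusted p = 0.0035), and the receptor NOTCH2 was lower in both (-0.5 and -0.65). KRT7 (0.62), YAP1 (0.38), GATA3 (-0.35), SDC1 (-0.62) and CYP11A1 (-0.44) also kept their direction after poly I:C and were called there. Of other phosphatidylserine receptors and ligands, TYRO3 (-0.42) and GAS6 (-0.49) were lower and ITGAV (0.36) was higher under mock. Of the 2 apoptosis genes called after poly I:C, RIPK1 (0.74) and CFLAR (0.56), CFLAR restrains caspase-8. CFLAR was also called higher under mock (0.62), where 1 of 19 apoptosis genes was lower. That mock call was not followed in the fits that left out 1 library. Of the genes in this paragraph, TYRO3 and GAS6 lost their call under mock without either mock knockout library or any 1 of the 4 poly I:C libraries. ITGAV lost its mock call without any 1 of the poly I:C libraries, and GATA3 without these or mock knockout replicate 2. After poly I:C, NOTCH2 lost its call without poly I:C control replicate 2 or either knockout library, and the other genes called there lost theirs without any 1 of the 4 poly I:C libraries. The chaperone HYOU1 (0.41) and the transcription factor XBP1 (0.31) were the 2 called members of the unfolded protein response list there.

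The lists given here were called by camera at the preset correlation and not with an estimated correlation. Under mock, phosphatidylserine receptors and ligands were lower (median -0.23, adjusted p = 0.01, and 0.43 with an estimated correlation), with 1 of 14 members higher and 3 lower (1 and 3 adjusted over the list alone). HAVCR1, the targeted gene, is 1 of the 3, and without it the list was not called (adjusted p = 0.4, 1 of 13 higher and 2 lower), a test chosen after the result was seen. That list lost its call without mock knockout replicate 1 (adjusted p = 0.099) or any 1 of the 4 poly I:C libraries (adjusted p = 0.1 to 0.11); its median was -0.04 without mock control replicate 1, and 1 member was lower without any 1 mock knockout or poly I:C library. Interferon genes and receptors under mock had a median of 0.12, a mean of -0.53 and a test that pointed up (adjusted p = 0.023, and 0.54 with an estimated correlation), so these differ in sign. Of the fits that left out 1 library, only that without mock control replicate 1 kept this call (adjusted p = 0.005, median 0.35); the others gave 0.053 to 0.26, with medians of 0.04 without mock control replicate 2, and 0.21 and 0.03 without mock knockout replicate 1 and 2.

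Extracellular matrix genes (median 0.15, adjusted p = 0.017, and 0.54 with an estimated correlation) were also called under mock, with 3 of 20 higher and 0 lower (6 and 1 adjusted over the list alone). The call was lost without mock control replicate 2 (adjusted p = 0.61, 3 higher and 3 lower, median 0.05) or mock knockout replicate 1 (0.059). Without mock control replicate 1, 7 were higher (median 0.27), and without mock knockout replicate 2 or any 1 poly I:C library 1 was. Of 8 replication-dependent histones 1 was lower and 0 higher (5 and 0 adjusted over the list alone; median -0.37, adjusted p = 0.017, and 0.54 with an estimated correlation). This call was lost without mock control replicate 2 (0.49, median -0.11) or mock knockout replicate 1 (0.053, 2 lower). Without mock control replicate 1, 3 were lower (median -0.56), and without mock knockout replicate 2 or any 1 poly I:C library edgeR called 0 (2 to 5 lower at an unadjusted p under 0.05).

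After poly I:C the unfolded protein response list had 2 of 17 members higher and 0 lower (2 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.0052, and 0.59 with an estimated correlation). The heat shock list had 1 of 9 higher and 0 lower (5 and 1 adjusted over the list alone; median 0.23, mean 0.05, adjusted p = 0.016, and 0.63 with an estimated correlation). The unfolded protein response counts were 7 higher without either mock control library and 4 without either mock knockout library, and those of heat shock 6 higher and 1 lower without either mock control library. Without any 1 poly I:C library edgeR called 0 in both lists (3 to 5 higher in each at an unadjusted p under 0.05).

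Of the haematopoietic markers 4 of 15 were tested and 2 exceeded 1 CPM, with CSF1R highest at 161 CPM. Of the endothelial markers these were 5 of 10 and 3, with CDH5 at 73.5 CPM, of the fibroblast markers 7 of 10 and 6, with COL1A1 at 54 CPM, and of HEK293-like or neuronal markers 2 of 10 and 1, with TUBB3 at 4.35 CPM. No list of markers was called by camera between knockout and control cells, while 2 fibroblast markers were higher under mock and 1 was lower after poly I:C.

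Of 15 genes near HAVCR1 on chromosome 5, 1 was lower in knockout cells under mock and 3 after poly I:C, and 0 were higher (3 and 4 lower and 0 higher adjusted over the list alone). CYFIP2 was called under mock (-0.61) and after poly I:C (-0.47), and LSM11 (-0.44) and CNOT8 (-0.63) after poly I:C, with list medians of -0.27 and -0.28 (camera adjusted p = 0.0028 for both, adjusted p = 0.43 and 0.22 with an estimated correlation). A hypothesis is that knockout cells lost a copy of this segment. The test took the median of the 40 expressed genes nearest in order. It was -0.17 under mock and -0.19 after poly I:C, at percentiles 0.73 and 1.1 of 12244 windows. These medians did not reach the bound set for a lost copy, yet few windows lay lower. The lowest window lay on chromosome 5 in both treatments (-0.24 and -0.39), so the test leaves the hypothesis open. Whether whole chromosomes, this one or others, shift between the genotypes was not tested. A local loss can therefore not be told apart from wider differences between the cells compared. CYFIP2 lost its call under mock without mock knockout replicate 2, and all 3 genes lost theirs after poly I:C without any 1 of the 4 poly I:C libraries, where 3 to 4 neighbours were lower at an unadjusted p under 0.05 and the median was -0.15 without knockout replicate 1. Under mock, 3 neighbours were lower without either mock control library, with a median of -0.18 without replicate 1.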
